A study of Schizosaccharomyces pombe with 5 samples.

How the data were processed

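The series measured RNA that came down with Slr1p, the fission yeast (Schizosaccharomyces pombe) homolog of the RNA-binding protein LARP1, by RNA immunoprecipitation and sequencing (RIP-seq). Per the labels, wild-type cells of strain yAS99 were grown in rich medium (YES) at 32 °C and cross-linked with formaldehyde. There were 5 libraries: 2 from immunoprecipitations with an antibody against Slr1p, 2 from total RNA input extracted with hot phenol, and 1 from an immunoprecipitation with non-immune rabbit IgG. Groups and replicate numbers were taken from the sample titles, which call the Slr1p and input libraries biological replicates. The IgG library had no replicate.

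The deposited values were raw read counts per gene, 1 library per file, with the same 6727 genes in each and 0 summary lines for unassigned reads. Per the labels' protocols, a directional NEBNext Ultra II kit was used, and fragments were read from both ends for 50 bp. Per the submitters' processing notes, which give no role or order, the authors used bcl2fastq 2.20, FastQC 0.11.5, Trim Galore, STAR 2.6.0c and HTSeq 0.6.1p2. The genome build, annotation, strand setting and treatment of multiply mapped reads are not given in the sources used here. Reads of near-identical gene pairs, which may include most ribosomal protein genes, may therefore have been lost or split. Reads of overlapping or antisense genes cannot be told apart with certainty. Ribosomal protein and elongation factor genes were taken to have a near-identical copy where another gene symbol shared their stem. Sequences were not compared. No coordinates are printed, because the build of the counts is not given.

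Gene names, biotypes, transcript lengths, GC content and sequences came from the RefSeq annotation of assembly ASM294v3, which may not be the one the authors used. Of the 6727 gene identifiers, 6592 matched it and 135 did not, and 4350 had a gene symbol. Genes without a symbol are named by the systematic identifier of the files.

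Total gene counts were 64236988 and 62802923 for input, 63392249 and 65859940 for the Slr1p immunoprecipitations, and 12882920 for IgG. Shares of counts are given with 95% Wilson intervals, which cover counting error only, because reads without molecular identifiers are not independent molecules. The Slr1p and input libraries were counted as separate samples because their titles call them biological replicates. Neither pair agreed within sampling noise, as copies of 1 library would: the chi-square statistic per degree of freedom was 45.2 over 6268 genes for the Slr1p libraries and 197 over 6269 genes for input. Pearson's r of log2(CPM + 1) across genes, which are not independent replicates, was 0.998 for the Slr1p pair and 0.996 for the input pair.

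Counts were tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood test, with TMM scaling, the package's default expression filter by group, and 1 mean per group over all 5 libraries. The filter removed 351 genes and left 6376. The fit had 2 residual degrees of freedom among libraries, moderated by 13.5 prior degrees of freedom, and a common biological coefficient of variation of 0.101. The single IgG library was assumed to vary like the replicated groups, so no comparison with IgG had a replicate check of the control. P-values were adjusted by Benjamini-Hochberg over all genes of a comparison, and genes under 0.05 were called. Expression is given as CPM, counts scaled by TMM to a common library total, as mean ± SD where n = 2, and log2 fold changes with their standard error (SE).

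Gene lists were fixed before the data were examined, as were the main test, the groups, the rule for named genes and most alternatives. The lists held cytosolic ribosomal proteins (40S and 60S), translation elongation and initiation factors, ribosome biogenesis, mitochondrial ribosomal proteins, proteasome, glycolysis and fermentation, histones, heat shock and core stress, meiosis and sporulation, cell wall and plasma membrane, mitochondrially encoded genes, snoRNA and snRNA, tRNA, rRNA, other noncoding RNA, Tf2 retrotransposons, and mRNAs whose annotated 5' end starts with a run of at least 5 pyrimidines from base 1, 2 or 3 (pyrimidine start). The tRNA and rRNA lists had 0 members among the genes counted. The mitochondrial list had been written for systematic identifiers and was matched by mitochondrial gene names instead, which gave 4 genes. In all, 6 symbols that the annotation gives to proteins of another function were left out, and keeping them changed 0 list calls. Lists with at least 5 tested members were tested with camera (limma 3.58.1), two-sided, with a preset inter-gene correlation of 0.01 and again with an estimated correlation, with adjustment over the lists of a comparison. All list calls at the preset value were lost with the estimated correlation, which rested on 2 residual degrees of freedom. Membership among genes higher in the Slr1p immunoprecipitation than in both controls was tested with Fisher's exact test, two-sided, adjusted over the lists.

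The named genes are slr1; in each Slr1p comparison, the 10 called genes with the largest rise and the 5 with the largest fall at a mean of at least 10 CPM with non-overlapping libraries; the 2 most abundant members of each list; the 5 largest rises and 3 largest falls among ribosomal protein and elongation factor genes; and the 5 largest rises and falls of IgG against input. Not every gene the rule takes is described in words. Other genes are said to have been chosen after their values were seen.

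The analysis was tested on simulated counts with the real library sizes and fitted spread, in which a set of genes was changed by a fold of 1.5, 2 or 4 in either direction. At a fold of 2, 86.6% were called for the Slr1p immunoprecipitation against IgG (58 of 67), 98.5% against input (66 of 67), and 86.6% for IgG against input (58 of 67), each among 6376 genes. At a fold of 1.5 these shares were 33.3%, 77.6% and 41.8%, and at a fold of 4 they were 92.4%, 98.5% and 93.8%. Unchanged groups were also simulated 20 times, to give the correlation and covariance that comparisons sharing libraries have with no effect. Alternatives were DESeq2 1.42.0 as another test, its size factors in edgeR, library totals alone, no expression filter, a stricter filter, nuclear protein-coding genes alone, only the libraries of the groups compared, the replicate number as a block, a minimum log2 change of 1, each replicate left out, ribosomal protein genes without a near-identical copy, and removal of the trend of each library with transcript length and GC content (mgcv 1.9.3).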

Results

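The series asked which RNAs associate with Slr1p in fission yeast, with non-immune IgG as the control of the immunoprecipitation. Slr1p is a homolog of LARP1, a protein known in animals for binding mRNAs that begin with a 5' terminal oligopyrimidine (TOP) motif, most of which encode ribosomal proteins and translation factors. There were 2 libraries of the Slr1p immunoprecipitation, 2 of total RNA input and 1 of the IgG immunoprecipitation. Gene counts totalled between 62802923 and 65859940 in each of the input and Slr1p libraries and 12882920 in the IgG library, which had no replicate.

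The mRNA of Slr1p itself (slr1, SPAC1527.03) stood at 131.8 ± 2.49 CPM (SD, n = 2) in the Slr1p immunoprecipitation, 89.5 ± 14.2 CPM (SD, n = 2) in input and 123.6 CPM in IgG. It was higher than in input, by a log2 fold change of 0.56 (SE 0.13, edgeR adjusted p = 0.00118). Against IgG its log2 fold change was 0.09 (SE 0.16, adjusted p = 0.625). With the trend of each library with transcript length and GC content removed it was 0.57 (adjusted p = 0.00422). With abundance in the trend as well it was 0.36 and not called (adjusted p = 0.0619). In IgG it was also higher than in input, at 0.47 (adjusted p = 0.0154). These values are for orientation, because an antibody against a protein need not bring down its mRNA.

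The libraries differed in the kinds of RNA they held. Mitochondrially encoded mRNAs made up 4.73% of the counts of the IgG library (95% Wilson interval 4.72 to 4.74%), against 0.000937% and 0.00154% in input and 0.00136% and 0.00107% in the Slr1p immunoprecipitation. The 7SL RNA of the signal recognition particle (srp7, SPNCRNA.98) took 0.621% of IgG counts (0.617 to 0.625%) and at most 9.04e-04% (8.33e-04 to 9.82e-04%) of any other library. The 13 snoRNA and snRNA genes took 0.330% of IgG counts (0.326 to 0.333%) and between 0.00929% and 0.0113% elsewhere. Nuclear protein-coding genes took 92.6% of IgG counts and between 98.3% and 98.6% of the others, and other noncoding RNA took between 1.39% and 1.69% of each library.

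**Figure D1:**
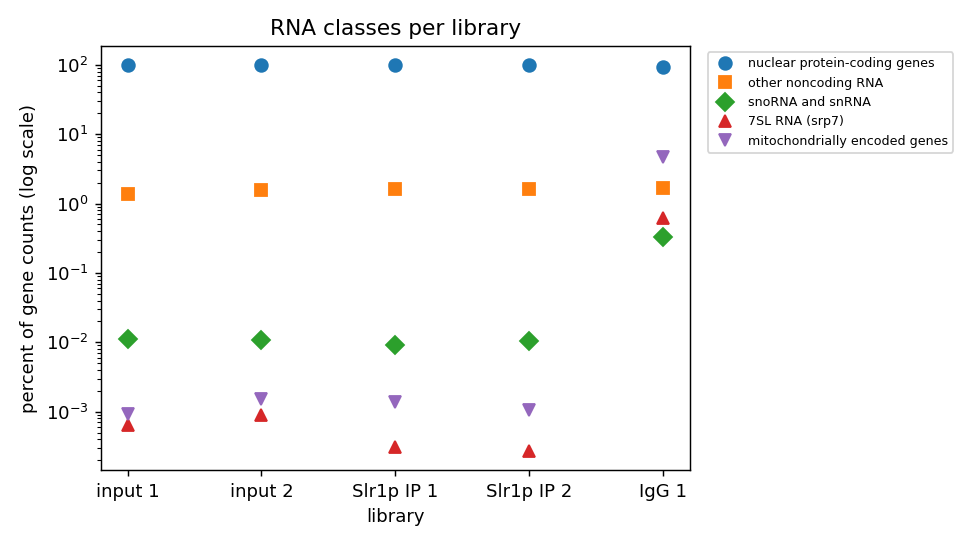
Percent of each library's gene counts (log scale) in 5 classes of RNA, 1 point per class and library, for 2 input, 2 Slr1p and 1 IgG libraries. Mitochondrially encoded genes, 7SL RNA, and snoRNA and snRNA lie higher in the IgG library (4.73%, 0.621% and 0.330%) than in any of the other 4.

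The comparison with IgG asks which RNAs exceeded the background of the immunoprecipitation, as far as the single IgG library, whose kinds of RNA differed from those of the other 4, stands for it. Ribosomal protein mRNAs were higher after Slr1p immunoprecipitation than in IgG. Of the 40S subunit genes 53 of 55 rose and 0 fell (54 and 0 adjusted over the list alone), with a median log2 fold change of 1.33. Of the 60S subunit genes 73 of 81 rose and 0 fell (73 and 0 adjusted over the list alone), with a median of 1.31. The mRNA of rpl4101 (SPAC3G6.13c), for the small 60S protein L41, stood at 2907 ± 579.7 CPM (SD, n = 2) after Slr1p immunoprecipitation and 501.1 CPM in IgG, a log2 fold change of 2.54 (SE 0.30, adjusted p = 2.35e-06). Next among the genes of these lists came rpl1902 at 2.24, rps3002 at 2.23, rps2502 at 2.21 and then rps2602. With the length, GC and abundance trend removed rpl4101 was at 1.56 and rpl1902 at 1.30.

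Camera called both ribosomal protein lists (adjusted p = 3.52e-11 and 8.29e-13), and neither was called when the correlation was estimated (adjusted p = 0.619 for both, with an estimated correlation). Most members have a copy by the stem of the gene symbol, with sequences not compared. Among those without one, the medians were 1.09 over 8 genes of the 40S list and 1.22 over 12 of the 60S list. With the length and GC trend removed the medians of the full lists were 0.82 and 0.79, and with abundance in the trend as well they were 0.43 and 0.47. These trends were fitted over all genes, ribosomal protein genes among them, so they may have taken up part of the lists' own difference. Genes outside both lists, of like length and abundance, had a median of 1.33 against IgG.

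Not all abundant ribosomal protein genes kept their calls under the alternatives. Fits without 1 Slr1p library took the spread from the input pair alone, on 1 residual degree of freedom. A call lost in such a fit, here and below, does not show that the Slr1p libraries differed. Against IgG, rpl8 had a log2 fold change of 1.25 (SE 0.31, adjusted p = 0.00206), or 0.17 and not called (adjusted p = 0.348) with the length, GC and abundance trend removed, and rpl26 stood at 6769 ± 1333 CPM (SD, n = 2) against 1945 CPM. The call of rps13 (1.15) was lost without Slr1p replicate 2 (adjusted p = 0.0527). That of rps102 (0.91) was lost without replicate 1 (0.96, adjusted p = 0.0731) and without replicate 2 (0.81, 0.137). Removing that trend took rps102 to -0.36 and rps13 to -0.12.

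Translation elongation factors went both ways against IgG, with 3 of 8 higher and 3 lower (3 and 3 adjusted over the list alone) and a median of 0.10 (camera adjusted p = 0.653). The mRNA of tef103, for elongation factor EF-1 alpha, was higher at 1.07 (SE 0.31), a call lost without Slr1p replicate 2 (0.91, adjusted p = 0.0853). The elongation factor 2 gene eft202 was lower at -0.94 (SE 0.21), which was lost without Slr1p replicate 1 (-0.84, adjusted p = 0.0525) and with the length and GC trend removed (-0.18). The lower values of tef3 (-0.82) and eft201 (-0.48) became 0.35 and 0.26 with that trend removed. Both calls were lost without Slr1p replicate 1 (-0.77 and -0.38, adjusted p = 0.167 and 0.353) and without replicate 2 (-0.91 and -0.64, adjusted p = 0.102 and 0.100).

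Other mRNA groups were also higher than in IgG. The proteasome list had 33 of 41 higher and 3 lower (33 and 3 adjusted over the list alone), a median of 1.05 and a camera adjusted p of 7.12e-07. Mitochondrial ribosomal proteins had 48 of 62 higher and 6 lower (49 and 6 adjusted over the list alone), a median of 0.78 and an adjusted p of 9.42e-05. Histones had 8 of 11 higher and 1 lower (8 and 1 adjusted over the list alone), a median of 1.03 and an adjusted p of 0.0217. None of the 3 was called when the correlation was estimated (adjusted p = 0.499, 0.499 and 0.619 with an estimated correlation). The proteasome ATPase gene rpt2 stood at 427.4 ± 0.547 CPM (SD, n = 2) against 194.5 CPM in IgG, while rpn2 was lower at -0.96 and at 0.062 with the length and GC trend removed. The mitochondrial ribosomal protein gene mrps16 had a log2 fold change of 1.70 (SE 0.18) and the histone H4 gene hhf1 of 1.30 (SE 0.23). With the length, GC and abundance trend removed they were at 0.86 and 0.017, the latter not called (adjusted p = 0.932). Removing the length and GC trend ended the call of mitochondrial ribosomal proteins (median 0.19, adjusted p = 0.337) and of histones (0.37, 0.370), and left the proteasome at 0.56 (7.96e-05, but adjusted p = 0.651 with an estimated correlation).

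Cell wall and plasma membrane genes were lower than in IgG, with 2 of 26 higher and 16 lower (2 and 16 adjusted over the list alone), a median of -0.94 and a camera adjusted p of 4.22e-06 (adjusted p = 0.499 with an estimated correlation). With the length and GC trend removed the median was -0.04 (adjusted p = 0.869). The proton pump gene pma1 was at -0.77 (SE 0.27), and at 0.78 with that trend removed, while ecm33 was at 0.59 (SE 0.21), and at 0.19 and not called with abundance in the trend as well (adjusted p = 0.248). Both calls were lost without Slr1p replicate 1 (-0.72 and 0.60, adjusted p = 0.184 and 0.169) and without replicate 2 (-0.87 and 0.54, adjusted p = 0.104 and 0.220). The snoRNA and snRNA list had 0 of 13 higher and 12 lower (0 and 12 adjusted over the list alone), a median of -2.48 and an adjusted p of 1.21e-12 (adjusted p = 0.499 with an estimated correlation). Its most abundant member snR30, the U17 snoRNA, stood at 28.3 ± 7.89 CPM (SD, n = 2) against 2167 CPM in IgG. All 4 mitochondrially encoded genes were lower, with a median of -11.79, and were too few for the list test.

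Several lists were not called against IgG by camera. Beside each stand the called genes, in parentheses those adjusted over the list alone, the median and the camera value. Translation initiation factors had 14 of 26 higher and 6 lower (14 and 6), median 0.43, adjusted p = 0.0607, and were called with the length and GC trend removed (median 0.50, adjusted p = 0.0409, but adjusted p = 0.651 with an estimated correlation). Ribosome biogenesis had 30 of 85 higher and 33 lower (30 and 33), median 0.03, adjusted p = 0.683, with a mean below 0. Glycolysis and fermentation had 4 of 19 higher and 3 lower (4 and 3), median 0.07, adjusted p = 0.632, and heat shock and core stress 8 of 24 higher and 5 lower (8 and 5), median 0.01, adjusted p = 0.304. Meiosis and sporulation had 37 of 148 higher and 47 lower (36 and 47), median -0.08, adjusted p = 0.653, with a mean above 0, and other noncoding RNA 431 of 1315 higher and 248 lower (410 and 239), median 0.33, adjusted p = 0.109. Tf2 retrotransposons had 1 of 8 higher and 3 lower (1 and 3), median -0.71, adjusted p = 0.632. With the length and GC trend removed the median of ribosome biogenesis was -0.013 and that of Tf2 retrotransposons 0.45, neither called (adjusted p = 0.725 and 0.966). Pyrimidine-start mRNAs had 159 of 469 higher and 185 lower (161 and 185), median -0.01, adjusted p = 0.632, and a median of 0.12 with that trend removed (adjusted p = 0.869). This list includes the pyruvate kinase gene pyk1, at -0.45 (SE 0.28, adjusted p = 0.175), and rpl13, at 1.05 (SE 0.28), a call lost without Slr1p replicate 2 (0.94, adjusted p = 0.0643) and with the length, GC and abundance trend removed (0.15, 0.388).

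Over all genes, 2166 of 6376 were higher and 2061 lower than in IgG by the edgeR quasi-likelihood test, and 1147 and 1194 of these by a log2 change of at least 1. The largest rise was that of ksh1 (SPBC530.16), at 14.6 ± 0.0805 CPM (SD, n = 2) against 0.944 CPM in IgG (log2 3.95, SE 0.36). It was followed by the noncoding RNA SPNCRNA.813 (3.69), rpl4101, the ubiquitin family gene SPBC800.12c (2.46) and ubi5, for a fusion of ubiquitin with a 40S ribosomal protein (2.46, and 1.09 with the length, GC and abundance trend removed). Next were sft2 (2.44), nop10 (2.32), SPNCRNA.800 (2.28), the metallothionein gene zym1 (2.27) and rpl1902. Of these 10 genes ksh1 was lower than in input (-1.57), as was sft2. The largest falls were the mitochondrially encoded cox2 (-12.00), cob (-11.89), cox1 (-11.69) and urf_a (-11.48), and srp7 (-10.94, SE 0.28). The median over all genes was 0.07 with TMM scaling and -0.05 with library totals alone, so changes are relative to a centre that moves by that much. With library totals alone 1701 genes were higher and 2091 lower, and with the length and GC trend removed 1782 and 1393, so which side holds more genes depended on the scaling.

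The comparison with input asks which RNAs were enriched over their abundance in the cell. Ribosomal protein mRNAs lay near their level in input as lists, with single genes on both sides. The 40S list had 17 of 55 higher and 8 lower (16 and 8 adjusted over the list alone), a median of 0.21 and a camera adjusted p of 0.226, and the 60S list 27 of 81 higher and 8 lower (25 and 7 adjusted over the list alone), a median of 0.25 and an adjusted p of 0.0648. The largest rise was that of rpp103 (SPCP1E11.09c), for the acidic ribosomal protein P1, from 665.9 ± 84.8 to 2183 ± 326.7 CPM (SD, n = 2 each), a log2 fold change of 1.71 (SE 0.20, adjusted p = 1.24e-06). Next were rpl13 (1.67), rpl1802 (1.58), rps1002 (1.56) and rpp203 (1.42). Of these 5, rpl13, rpl1802 and rps1002 were also higher than in IgG, while rpp103 and rpp203 stood at 0.14 and -0.18 against IgG.

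The largest falls among ribosomal protein genes, rps1501 (-0.77), rpl2002 (-0.76) and rps1502 (-0.76), were lost as calls without Slr1p replicate 1 (-0.68, -0.66 and -0.66, adjusted p = 0.132, 0.127 and 0.140). Without input replicate 1, rpl2002 was at -0.50 and rps1502 at -0.46. The list tests also depended on that library, since without it the medians were 0.41 for 40S (adjusted p = 0.00376) and 0.42 for 60S (3.62e-04), and without input replicate 2 they were -0.010 and 0.066. Both calls were lost with an estimated correlation, which rested on 1 residual degree of freedom and was 1 for both lists, so that this loss decides nothing. The 60S list was called without Slr1p replicate 1 (0.31, adjusted p = 0.0130), with DESeq2 (0.23, 0.0135) and with library totals alone (0.25, 0.00970). The first and last of these were lost with an estimated correlation (adjusted p = 0.983 for the last), which was not run for DESeq2. For the first that estimate again rested on 1 residual degree of freedom.

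Translation elongation factors had 5 of 8 higher and 0 lower (5 and 0 adjusted over the list alone) and a median of 0.63 (camera adjusted p = 0.226), and the median was 0.015 over the 3 genes without a near-identical copy, too few for the list test. The mRNA of tef103 rose from 3389 ± 509.0 to 8600 ± 1114 CPM (SD, n = 2 each), a log2 fold change of 1.34 (SE 0.24, adjusted p = 1.40e-04). That of tef3 was called at 0.66 with all libraries and in none of the fits without 1 of them (0.71 and 0.57 without Slr1p replicates 1 and 2, 0.55 and 0.77 without input replicates 1 and 2). Initiation factors had 12 of 26 higher and 10 lower (12 and 10 adjusted over the list alone), a median of 0.24 and an adjusted p of 0.798. The mRNA of tif1, for the helicase eIF4A, was lower at -1.86 (SE 0.22), and tif303, for subunit c of eIF3, was higher at 1.20 (SE 0.17). In IgG against input tif1 was at -2.25 and tif303 at 2.22. After Slr1p immunoprecipitation tif1 was at 0.39 against IgG and not called, and tif303 was lower than in IgG, at -1.02.

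Ribosome biogenesis genes were higher than in input, with 61 of 85 higher and 9 lower (61 and 9 adjusted over the list alone), a median of 0.63 and a camera adjusted p of 5.10e-07 (adjusted p = 0.929 with an estimated correlation). The pseudouridine synthase gene cbf5 stood at 899.8 ± 1.75 CPM against 546.7 ± 1.28 CPM in input (SD, n = 2 each; log2 0.72). Its call was lost without Slr1p replicate 1 (0.69, adjusted p = 0.0600) and without replicate 2 (0.71, 0.0546). The fibrillarin gene fib1 was at -0.10 (SE 0.16). The list was also higher in IgG than in input, with a median of 0.84, and cbf5 stood at 3389 CPM in IgG.

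Histone genes were lower than in input, with 0 of 11 higher and 11 lower (0 and 11 adjusted over the list alone), a median of -0.79 and a camera adjusted p of 0.0116 (adjusted p = 0.929 with an estimated correlation). The mRNA of the histone H3 gene hht2 stood at 1409 ± 282.1 CPM in input, 615.1 ± 35.9 CPM after Slr1p immunoprecipitation (SD, n = 2 each) and 301.7 CPM in IgG. The histone H4 gene hhf1 was at -0.64, at -0.58 and not called without Slr1p replicate 1 (adjusted p = 0.120), and at -0.42 without input replicate 1. Other noncoding RNAs had 555 of 1315 higher and 216 lower (546 and 207 adjusted over the list alone), a median of 0.40 and an adjusted p of 0.00204 (adjusted p = 0.929 with an estimated correlation). With the length and GC trend removed that list was at 0.36 and not called (adjusted p = 0.0514).

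The remaining lists were not called against input by camera. Mitochondrial ribosomal proteins had 23 of 62 higher and 23 lower (23 and 23), median -0.02, adjusted p = 0.798, and the proteasome 13 of 41 higher and 19 lower (13 and 19), median -0.19, adjusted p = 0.832. Glycolysis and fermentation had 3 of 19 higher and 7 lower (3 and 7), median -0.16, adjusted p = 0.825 (median 0.022 with the length and GC trend removed), and heat shock and core stress 3 of 24 higher and 11 lower (2 and 11), median -0.26, adjusted p = 0.249. Meiosis and sporulation had 41 of 148 higher and 42 lower (40 and 40), median 0.02, adjusted p = 0.949, with a mean below 0, and cell wall and plasma membrane 5 of 26 higher and 14 lower (6 and 14), median -0.47, adjusted p = 0.226. For snoRNA and snRNA the values were 3 of 13 higher and 2 lower (3 and 2), median -0.03, adjusted p = 0.798, with a mean above 0. Tf2 retrotransposons, whose copies are near-identical, had 2 of 8 higher and 1 lower (2 and 1), median 0.35, adjusted p = 0.589. The most abundant, Tf2-2, was higher at 2.56 (SE 0.22), and the next, Tf2-11, was lower at -1.32 (SE 0.34). In IgG against input they were at 3.20 and 1.54, and against IgG at -0.63 and -2.86. Pyrimidine-start mRNAs had 128 of 469 higher and 209 lower (129 and 211), median -0.20, adjusted p = 0.226. The 4 mitochondrially encoded genes had a median of -0.01.

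Over all genes, 2230 were higher and 2183 lower than in input, and 804 and 1051 of these by a log2 change of at least 1. Removal of the length and GC trend gave 2448 higher and 2012 lower, and DESeq2 size factors 2184 and 2221. The largest rise was that of snp27 (SPCC162.01c), a component of the spliceosomal U4/U6.U5 particle, from 10.6 ± 1.91 to 104.7 ± 2.63 CPM (SD, n = 2 each; log2 3.30, SE 0.14). Next were SPNCRNA.1048 (3.25), SPBC27.05 (3.20), the nucleoporin gene nup211 (2.90), ctr1 (2.83), prl62 (2.82), SPAC607.02c (2.74), mto1 (2.72), the initiation factor gene tif52 (2.70) and cgr1 (2.66). Of these 10 genes cgr1 was higher than in IgG (0.41), and the other 9 stood at -0.20 or lower against IgG. The mRNA of tif52 was at 151.9 ± 29.5 CPM in input, 984.2 ± 17.4 CPM after Slr1p immunoprecipitation (SD, n = 2 each) and 4637 CPM in IgG. The largest falls were coa3 (-5.50), edc1 (-5.11), elo2 (-5.10), ema19 (-4.88) and SPNCRNA.742 (-4.58), each also lower than in IgG. The mRNA of elo2 (SPAC1B2.03c), of a fatty acid elongase family, was at 234.3 ± 10.5 CPM in input (SD, n = 2), 7.90 and 5.77 CPM in the Slr1p libraries and 113.7 CPM in IgG.

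**Figure D2:**
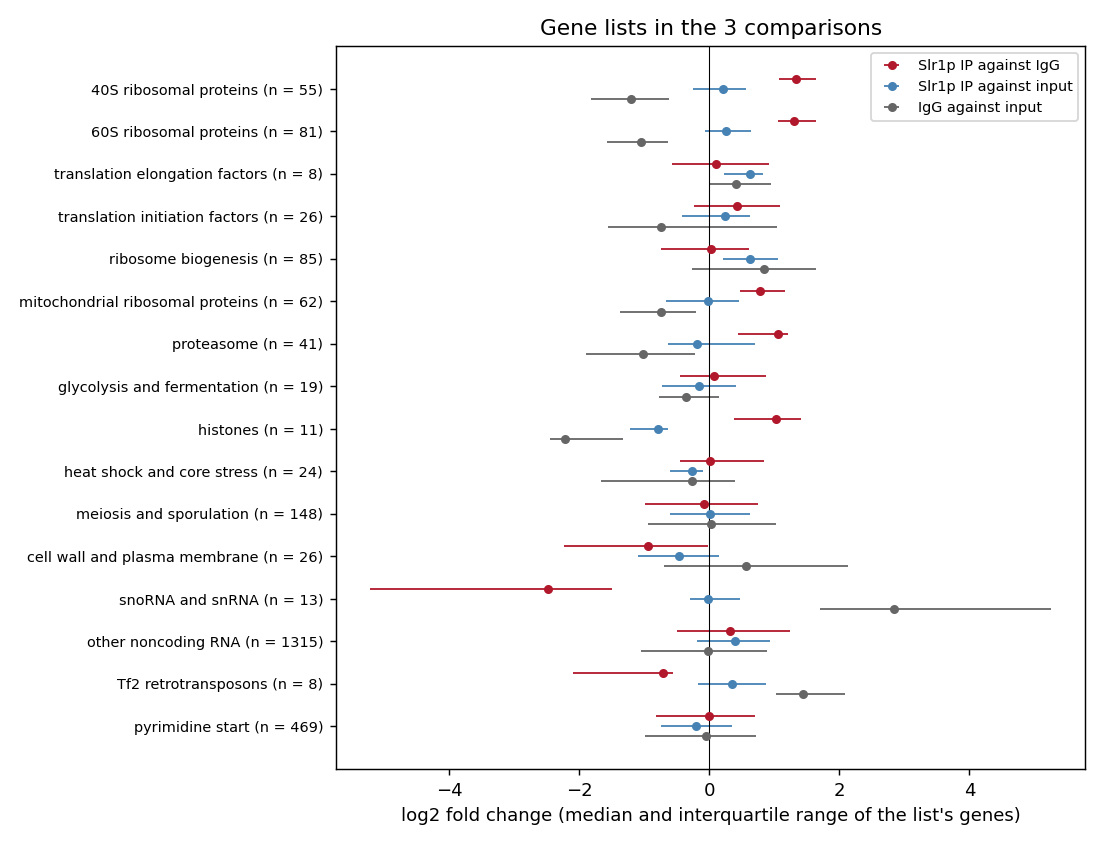
Median log2 fold change (points) and interquartile range (lines) of the genes of each fixed list with at least 5 tested members, for the Slr1p immunoprecipitation against IgG, the same against input, and IgG against input, with the number of tested genes as n. The 40S and 60S ribosomal protein lists lie at 1.33 and 1.31 against IgG, at 0.21 and 0.25 against input, and at -1.21 and -1.05 for IgG against input.

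Higher levels than in both controls were found for 862 genes after Slr1p immunoprecipitation, and lower levels than in both for 901. Ribosomal proteins were over-represented among the 862 by Fisher's exact test. They held 15 of 55 genes of the 40S subunit (7.44 by chance, adjusted p = 0.0280) and 23 of 81 of the 60S subunit (10.95 by chance, adjusted p = 0.00231). The numbers by chance were taken over all genes. Other genes of like length and abundance, with a median of 1.33 against IgG, were not tested in this way. Fisher's test takes genes as independent, whereas camera estimated correlations between members of 0.827 and 0.851 against input and 0.830 and 0.860 against IgG, with its calls against IgG lost at these, and 8 of 55 and 12 of 81 members lack a near-identical copy, so these p-values may be too small. Mitochondrial ribosomal proteins were over-represented as well, with 21 of 62 (8.38 by chance, adjusted p = 5.75e-04), as were other noncoding RNAs, with 219 of 1315 (177.8 by chance, adjusted p = 0.00231). Against input, however, 23 mitochondrial ribosomal protein genes were higher and 23 lower. Against IgG their list lost its camera call with the length and GC trend removed (median 0.19). Fisher's test was not repeated with that trend removed. Meiosis and sporulation genes were under-represented, with 7 of 148 (20.01 by chance, adjusted p = 0.00254). Their median level over all libraries was 3.83 CPM, and how far low counts limited their calls was not tested. The over-represented other noncoding RNAs had a median of 3.44 CPM. The mRNAs of rpl13, rpl1802, rps1002, rps2602 and tef103 were among the 862. The other lists did not pass this test. Among them, 2 of 8 elongation factors, 3 of 26 initiation factors, 18 of 85 ribosome biogenesis genes, 10 of 41 proteasome genes, 1 of 24 stress genes, 1 of 8 Tf2 retrotransposons and 47 of 469 pyrimidine-start mRNAs were higher than in both. That number was 0 of 19 for glycolysis and fermentation, 0 of 11 for histones, 0 of 26 for cell wall and plasma membrane, 0 of 13 for snoRNA and snRNA and 0 of 4 for mitochondrially encoded genes.

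Both comparisons share the Slr1p libraries. The number of genes higher than both controls fell without either Slr1p library and rose without either input library. Such fits took the spread from the remaining replicated pair, so these shifts do not show that the genes rested on a single library. Independent lists of 2166 and 2230 genes, as called higher than IgG and than input, would share 757.6 genes. Unchanged groups simulated with the shared libraries gave 0 in each of 20 draws. These zeros say nothing of sharing, because at most 2 genes were called in any simulated comparison. Across 6376 genes, which are not independent replicates, the log2 fold changes of both comparisons had a correlation of 0.210, against 0.211 in the simulation, and a covariance of 0.376, against 0.0167. Part of the overlap may come from the shared libraries, which are too few to split.

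IgG against input sets the background beside input, and any difference in how RNA was selected for the IgG library would enter it and the Slr1p comparison with IgG alike. Of 6376 genes 2176 were higher and 2325 lower in the IgG library, and 2190 and 1929 with library totals alone. The largest rises were cox2 (12.05), cob (11.96), cox1 (11.63), urf_a (11.16) and srp7 (9.54, SE 0.26). The largest falls were ksh1 (-5.51, SE 0.35), the ATP synthase subunit genes atp17 (-4.63) and atp14 (-4.04), isp3 (-4.15) and the GDP-mannose transporter gene vrg4 (-4.05). The 40S list was lower, with 1 of 55 higher and 40 lower (1 and 40 adjusted over the list alone) and a median of -1.21, and the 60S list, with 4 of 81 higher and 62 lower (4 and 62 adjusted over the list alone) and a median of -1.05. Histones had 0 of 11 higher and 10 lower (0 and 10 adjusted over the list alone) (median -2.22), the proteasome 6 of 41 higher and 29 lower (6 and 29 adjusted over the list alone) (-1.02) and mitochondrial ribosomal proteins 7 of 62 higher and 38 lower (7 and 38 adjusted over the list alone) (-0.74). Ribosome biogenesis was higher, with 52 of 85 higher and 19 lower (53 and 19 adjusted over the list alone) (0.84), as were cell wall and plasma membrane, with 14 of 26 higher and 7 lower (14 and 7 adjusted over the list alone) (0.56), and snoRNA and snRNA, with 12 of 13 higher and 1 lower (12 and 1 adjusted over the list alone) (2.85). Camera called these 8 lists (adjusted p at most 0.00485), and none when the correlation was estimated (adjusted p at least 0.669 with an estimated correlation). With the length and GC trend removed cell wall and plasma membrane turned to a median of -0.43 and was not called (adjusted p = 0.205), and mitochondrial ribosomal proteins, at -0.28, lost their call (0.123).

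The other lists were not called in IgG against input. Elongation factors had 3 of 8 higher and 1 lower (3 and 1), median 0.41, adjusted p = 0.497, and initiation factors 9 of 26 higher and 16 lower (9 and 16), median -0.75, adjusted p = 0.244. Glycolysis and fermentation had 3 of 19 higher and 7 lower (3 and 6), median -0.35, adjusted p = 0.497, and heat shock and core stress 5 of 24 higher and 11 lower (5 and 11), median -0.26, adjusted p = 0.0539, which was called with the length and GC trend removed (-0.43, adjusted p = 0.0188, but adjusted p = 0.664 with an estimated correlation). Meiosis and sporulation had 47 of 148 higher and 42 lower (45 and 41), median 0.03, adjusted p = 0.690, with a mean below 0. Other noncoding RNA had 378 of 1315 higher and 343 lower (367 and 320), median -0.01, adjusted p = 0.564, although camera's direction was up, and a median of 0.17 with that trend removed (adjusted p = 0.117). Tf2 retrotransposons had 3 of 8 higher and 0 lower (3 and 0), median 1.44, adjusted p = 0.362, and pyrimidine-start mRNAs 164 of 469 higher and 186 lower (164 and 186), median -0.05, adjusted p = 0.690. The 4 mitochondrially encoded genes were all higher, with a median of 11.79.

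The immunoprecipitations with Slr1p antibody and with IgG departed from input in part together. Of the 2230 genes higher after Slr1p immunoprecipitation than in input, 1280 (57.4%) were also higher in IgG, and of the 2183 lower ones 1380 (63.2%) were also lower. Independent lists would share 761.1 and 796.0 genes, and unchanged groups simulated with shared input libraries gave 0 and 0, again from at most 2 called genes, so that these zeros decide nothing. The log2 fold changes correlated at 0.394 across 6376 genes, against 0.216 in the simulation, and their covariance was 0.752 against 0.0171. The shared input libraries may add to the overlap and are too few to split. The simulated covariance, at most 0.0236, argues against counting and replicate noise of the shared input libraries as the main cause of the shared changes. A trait common to both input libraries was not simulated and stays open.

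**Figure D3:**
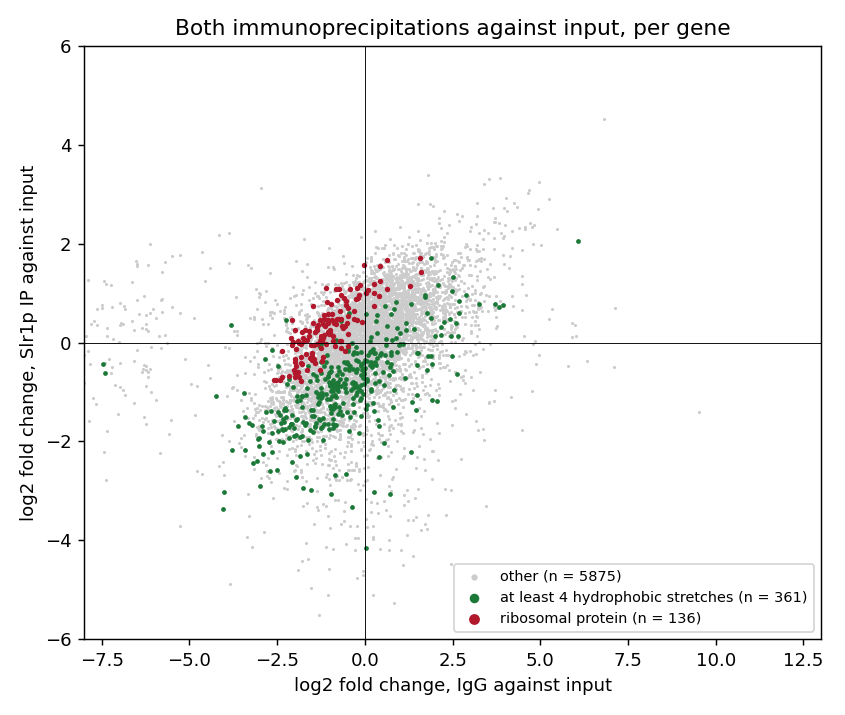
Log2 fold change against input of each tested gene in the IgG library (horizontal axis) and after Slr1p immunoprecipitation (vertical axis), with 136 ribosomal protein genes in red, 361 genes whose protein has at least 4 hydrophobic stretches in green and 5875 other genes in grey. These numbers leave out the 4 mitochondrially encoded genes and include 35 genes that lie outside the axes and are not drawn. The correlation over 6376 genes is 0.394, and the ribosomal protein lists have medians of -1.21 and -1.05 on the horizontal axis and 0.21 and 0.25 on the vertical one.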

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

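All tests with a length and GC trend removed were chosen after the results were seen, except for the ribosomal protein and elongation factor medians, as were those with abundance in the trend and those with crossed replicate numbers. The other alternatives were planned. Counts of called genes, the medians of the ribosomal protein and elongation factor lists and the slr1 values kept their direction and side of the threshold, and counts stayed within 1.5 times, under all alternatives except those named here, and the cause of the exceptions was not tested. With a minimum log2 change of 1 the counts fell by construction, to 1147 and 1194 genes (Slr1p against IgG), 804 and 1051 (Slr1p against input), 1358 and 1476 (IgG against input) and 149 (higher than both controls). Leaving out 1 library gave 463 to 1058 genes higher than both controls, the lowest without Slr1p replicate 2, and the other planned and added alternatives 606 to 1008. The single library left in a group was then assumed to vary like the others. The median against input ranged from -0.010 to 0.41 for 40S and from 0.066 to 0.42 for 60S proteins with 1 library left out. The 40S list, not called with all libraries, was called without input replicate 1 (0.41, adjusted p = 0.00376, range over alternatives 0.00376 to 0.977). The 60S list, not called either, was called without Slr1p replicate 1 (0.31, 0.0130), without input replicate 1 (0.42, 3.62e-04), with library totals (0.25, adjusted p = 0.00970), DESeq2 (0.23, 0.0135) and crossed numbers (0.25), with adjusted p between 3.62e-04 and 0.640 over all its alternatives. These gained calls were lost with an estimated correlation, which was not run for DESeq2. In the fits without 1 library and with crossed numbers that estimate rested on 1 residual degree of freedom. It was 1 for both lists without input replicate 1, so the loss of calls in these fits decides nothing. Over the 3 elongation factor genes without a near-identical copy, too few for the list test, the median was 0.14 against IgG and moved from 0.63 to 0.015 against input. For slr1 against IgG the length and GC trend removed gave 0.57 (adjusted p = 0.00422, range over alternatives 0.00422 to 0.925). With abundance in the trend as well slr1 was at 0.36 and not called (adjusted p = 0.0619). Its value was below 0 with library totals (-0.03), as was the elongation factor median (-0.02). The 40S median against input was at -0.041 with abundance in the trend and -0.010 without input replicate 2. None of these values below 0 was called.

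Of the values of named genes, 12, all against IgG, changed sign and were called with all libraries or under the alternative. With the length and GC trend removed these were tef3 (0.35), rpn2 (0.062), pma1 (0.78), Tf2-2 (0.58) and eft201 (0.26). With abundance in the trend they were rps102 (-0.36), rps13 (-0.12), mrpl32 (-0.17), hht2 (-0.014), prl53 (-0.95), Tf2-2 (0.92) and eft201 (0.28). Over 115 named-gene results and their alternatives, 1438 values kept direction and side of the threshold, 37 gained and 51 lost a call, and 24 changed sign without a call in either fit.

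The sample titles number the Slr1p and input libraries alike but do not say whether like numbers shared a culture. Deviations from the group means correlated at -0.156 (Spearman -0.189) across 6376 genes. With 1 difference per group this cannot decide whether the libraries are paired. With the replicate block, 2126 genes were higher and 2081 lower than in input, the 40S and 60S medians were 0.21 and 0.25, and slr1 was at 0.57. Of the named genes 1, tef3, lost its call under the block (0.66, adjusted p = 0.103). With the numbers crossed the counts were 2351 and 2266. At a simulated fold of 1.5, 33.3% of changed genes were called against IgG and 77.6% against input, and the share due to depth was not separated from that due to the single IgG library.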

Other observations

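All tests of explanations in this part, and the sets of genes and bounds they use, were chosen after the results were seen, except that removal of the length and GC trend and leaving out 1 library had been planned as alternatives for the 40S and 60S medians.

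Of 361 genes whose protein has at least 4 hydrophobic stretches (19 residues with a mean Kyte-Doolittle hydropathy of at least 1.6), as many membrane proteins have, 187 (51.8%) were lower in both immunoprecipitations than in input. Of the 361, 28 were higher and 273 lower after Slr1p immunoprecipitation than in input, with a median log2 fold change of -0.88 (camera adjusted p = 5.21e-17, adjusted p = 0.198 with an estimated correlation). In IgG against input 76 were higher and 201 lower, with a median of -0.69 (adjusted p = 4.66e-04, adjusted p = 0.766 with an estimated correlation). Of 1082 genes with 1 to 3 stretches 246 were higher and 515 lower after Slr1p immunoprecipitation (median -0.29, adjusted p = 3.37e-04, adjusted p = 0.124 with an estimated correlation), and 375 higher and 471 lower in IgG (median -0.19, adjusted p = 0.560, not called). Among 3566 genes without such a stretch the medians were 0.08 and -0.00. Genes picked after their values were seen were sec61, the channel of the translocon (-1.46 after Slr1p immunoprecipitation and -2.08 in IgG), sec63 (-1.11 and -0.83), and, with 1 stretch each, the chaperone gene bip1 (-2.53 and -0.92) and the disulfide isomerase gene pdi1 (-0.79 and -1.58) of the endoplasmic reticulum. Exceptions among genes picked in the same way were pma1, higher in both (0.93 and 1.70, the former not called without Slr1p replicate 2, 0.84, adjusted p = 0.0605), hmg1 (-0.19, adjusted p = 0.171, and 0.75) and, not called in either, ole1 with 2 stretches (0.20 and 0.35) and erg11 with 1 (-0.28 and -0.13).

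RNAs that carry no long poly(A) tail stood apart in the IgG library. Of 20 such RNAs, which were 4 mitochondrial and 16 nuclear ones (snoRNA and snRNA, 7SL, and the RNAs of RNase P and RNase MRP), 17 were above 2 times every other library in IgG, as they would be if library preparation or selection had let such RNAs into that library alone. The RNase P RNA rrk1 stood at 129.6 CPM in IgG against 4.63 and 4.98 CPM in input and 2.38 and 2.49 CPM after Slr1p immunoprecipitation. Mitochondrial RNA carried into the immunoprecipitation stays open for the 4 mitochondrial RNAs. Transcript length and GC content are argued against as the whole cause, since the median of the set was 4.86 before and 5.27 after that trend was removed (19 RNAs with a length). Different selection of RNA in the IgG library may be the cause, in which case the other comparisons with IgG would hold it too, and binding of these RNAs to IgG or beads, which the single library leaves untested, stays open.

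Higher ribosomal protein mRNAs than in IgG may not need binding to Slr1p. Lists of other genes matched on length and abundance (10000 lists, drawn from the 10 nearest genes of each, 136 different genes in all) had a median log2 change of 1.33 against IgG, with 1.04 as the lowest and 1.40 as the highest, against 1.32 for the 136 ribosomal protein genes. The IgG against input median (-1.15) made up 86.6% of that difference, while length and GC content alone are argued against as the whole cause, since removing their trend left 0.80 (quartiles 0.54 to 1.09). Against input the matched lists were at -0.014 (highest 0.20) and the ribosomal protein genes at 0.22. The 40S and 60S medians, however, went from 0.21 and 0.25 to -0.041 and 0.0022 with the length, GC and abundance trend removed. That trend was fitted with the ribosomal protein genes included, so it may have taken up part of their own difference and cannot decide. Without input replicate 2 the medians were -0.010 and 0.066. The smaller difference against input was not called, and short and abundant transcripts stay open as its cause. Association of some ribosomal protein mRNAs with Slr1p, with 38 of the 136 higher than in both controls, stays open as a hypothesis.

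The departures from input that both immunoprecipitations share could come from how their RNA was obtained, since input was extracted with hot phenol. Their covariance was 0.752, against 0.0171 in the simulation (highest 0.0236), which argues against noise of the shared input libraries as the cause. A trait common to both input libraries, such as their extraction, was not simulated and stays open. Length and GC content are argued against by 0.751 with that trend removed (0.730 before, over the same 6307 genes). A candidate explanation is that mRNAs bound to membranes stayed out of the lysate: 51.8% of the genes with at least 4 hydrophobic stretches were lower in both immunoprecipitations, against 20.4% of those with none and 32.3% of those with 1 to 3. It covers part of the pattern, since 187 of the 1380 genes lower in both have at least 4 stretches and 537 have at least 1. No biological explanation was tested, because the design has no group for it.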
